A study of Danio rerio with 9 samples.

How the data were processed

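HiCAR reports contacts of accessible chromatin: nuclei are cross-linked, open chromatin is tagged with Tn5 carrying an adaptor, and the adaptor is ligated to nearby DNA ends cut by a restriction enzyme, so that each sequenced molecule links an open site to a sequence close to it in space. Per the labels, it was applied to caudal fins of adult wild type zebrafish of the outbred Ekkwill strain, taken at 0, 1 or 4 days post amputation (dpa). Each of the 9 samples was a pool of 10 fins, with 3 pools per time point.

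The deposited processed data used here are 3 lists of called interactions, 1 per time point. Their time points were taken from the names of the lists, which match the sample titles, since no column names a time. Each row is a pair of 10 kb bins on 1 chromosome. Per the file headers, it gives the deposited contact count of the pair, the expected count under the authors' background model, a false discovery rate (FDR, a q-value) given by the authors, the cluster of neighbouring called pairs it belongs to, and a deposited −log10 p of the whole cluster. Per the submitters' processing notes, BWA and the build danRer11 were used. The version of BWA, the interaction caller, the terms of the background model and the way the 3 pools of a time point were combined are not given in the sources used here. In all 3 lists the FDR lay under 0.01, the count was at least 12 and the count was at least 2 times the expected count. Pairs marked as singletons, with no called neighbour, had an FDR of at most 0.0001. Pairs below these limits are not in the lists, so an interaction that was not called has no value here.

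The lists hold 1 value per time point and no replicate values. No test across replicates, SD or p-value between time points could be made, and leaving out a replicate was not possible. All comparisons are therefore between lists. No interval at the 95% level covers the spread between pools. Exact Poisson intervals for a count over its expected count and exact conditional binomial intervals for a ratio between times cover counting error alone. Order-statistic intervals for medians and bootstrap intervals for differences of medians treat called pairs as independent. Neighbouring called pairs are not independent, so these intervals are likely too narrow. Sequencing depth is unknown, since the counts cover called pairs only; the counts at called pairs summed to 909221 at 0 dpa, 562191 at 1 dpa and 861126 at 4 dpa and move with how much was called.

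An interaction had a counterpart at another time if a called pair there had both anchors within 1 bin of its own. Spans are distances between bin starts. For pairs called in the same bins at both times, the ratio of observed over expected counts was taken between times, with 1.5-fold as the size limit. These choices and most alternatives were fixed before the data were examined: the identical pair of bins, anchors within 2 bins, an FDR of at most 0.0001 in all lists or on one side, a count of at least 20, lists of equal length, no singletons, cluster summits, spans of at most 200 kb, centred ratios and raw counts. Alternatives and results added after the lists were seen are named as such in the closing section.

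Gene assignment had been planned, with gene lists, promoter results and motif density. These were not run, because no annotation or sequence of danRer11 was used here and coordinates of another build cannot be mixed with it. The naming rule, written for genes, was adapted to bins after the lists were seen. It took the 8 pairs with the highest observed over expected count in each set (count of at least 20, 1 per cluster), the 3 anchor bins with the most interactions at each time, and the 4 largest rises and 4 largest falls among pairs called in all lists. The 4 anchors with the largest rise or fall in each comparison were chosen after their values were seen. Positions are 1-based in danRer11.

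A reference model for counting error was added after the lists were seen. It gives each of the 43117 bin pairs called in any list a single observed over expected strength at all times, draws Poisson counts 100 times and applies the limits seen in the lists. It was run in 2 forms. The first had no further term and gave a 0 dpa list of 21059 interactions against 28421 deposited. After that result was seen, a form with a list-wide strength factor was fitted (1 at 0 dpa and 0.888 at both 1 and 4 dpa) and gave 25540. It was further off in the other lists. At 1 dpa the forms without and with factors gave 19562 and 17374 interactions against 18712 deposited. At 4 dpa they gave 25284 and 22720 against 26988. The forms differ on whether several counts lie above the model, so values of both are given. The form with factors was then refitted to 3 sets of lists drawn from itself with no change between times. There, the drawn lists held 1.58 times the refitted model's count of 1 dpa interactions without a 0 dpa counterpart, 1.52 times for 4 dpa, 1.36 times for those called at both, and 1.63 times for 0 dpa interactions without a later counterpart. The same check of the form without factors, added last, gave 1.40, 1.52, 1.3 and 1.63 times. The model is thus too low for such counts by about these factors even where nothing changed. An earlier and simpler simulation of shared pairs, which ignored that both counts had to pass the calling limits, gave 593 rises and 1281 falls of 1.5-fold for 1 dpa and 513 and 1914 for 4 dpa, more than were observed.

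The overlap and ratio steps were tested on simulated data. In a copy of the 0 dpa list of 28421 pairs, 200 pairs were moved far away. The others were shifted by at most 1 bin, which the matching rule allows. All 200 were found, with 0 false calls. That outcome follows from these settings, so it checks the code and not how often true counterparts are missed. Of 200 pairs given a 3-fold change among the 15730 pairs shared by 0 and 4 dpa, 200 passed 1.5-fold, as did 1055 pairs simulated without change, and 192 of 200 intervals held the true ratio. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.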

Results

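Chromatin contacts of the zebrafish caudal fin were measured by HiCAR in uninjured fins at 0 dpa and in regenerating fins at 1 and 4 dpa, with 3 pools of 10 fins per time point. The deposited lists held 28421 called interactions at 0 dpa, 18712 at 1 dpa and 26988 at 4 dpa, with 1 list per time point and no replicate values. The 1 dpa list thus had 65.8% and the 4 dpa list 95% as many interactions as the 0 dpa list. The difference at 1 dpa was seen on each of the 25 chromosomes, from 0.609 times as many on chromosome 9 to 0.741 times on chromosome 4. At 4 dpa the ratio ran from 0.814 on chromosome 1 to 1.03 on chromosome 25. The chromosomes of a list share its depth and pools, so they are not replicates. The median count behind a called pair was 29, 26 and 28 at 0, 1 and 4 dpa, and the median observed over expected count was 3.83, 4.12 and 3.89. Interactions joined 29134 anchor bins at 0 dpa, 20969 at 1 dpa and 28039 at 4 dpa. The number of calls depends on sequencing depth, which the lists do not give, and the spread between the 3 pools of a time point could not be measured.

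Called interactions spanned longer distances in regenerating fins. The median span was 70 kb at 0 dpa (95% interval 60 to 70), 80 kb at 1 dpa (80 to 80) and 90 kb at 4 dpa (90 to 100). Interactions of at most 50 kb made up 44.4% of the 0 dpa list, 36.9% at 1 dpa and 32.0% at 4 dpa. Those over 200 kb and up to 1 Mb made up 12.1%, 13.9% and 18.2%. In numbers, interactions of this longer class went from 3425 at 0 dpa to 2599 at 1 dpa and 4911 at 4 dpa, while those of at most 50 kb went from 12624 to 6906 and 8644.

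Most uninjured contacts were also called during regeneration. Of the 0 dpa interactions, 18458 (64.9%) had a counterpart at both 1 and 4 dpa, and 10726 bin pairs were identical in all 3 lists. Pairs over very long distances with counts far above expected were among them. A pair on chromosome 4, between 54470001–54480000 and 71620001–71630000, had 208, 152 and 149 counts at 0, 1 and 4 dpa, or 206, 150 and 147 times the expected count. A pair on chromosome 16, between 44700001–44710000 and 53540001–53550000, had 129, 130 and 115 times the expected count. Both were singled out after their values were seen. Their expected counts were so low that these ratios nearly equal the counts, and they are not comparable with ratios of nearer pairs. For such pairs, the order of the sequence in the assembly or the Ekkwill genome could not be told apart from ordinary contacts.

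The study's design asks which interactions appear in regenerating fins and are absent from uninjured fins. At 1 dpa, 2160 interactions (11.5% of that list) had no 0 dpa counterpart. At 4 dpa there were 5521 (20.5%), and 909 of the 1 dpa interactions without a 0 dpa counterpart had a counterpart at 4 dpa. In the other direction, 4767 interactions of uninjured fins (16.8%) had no counterpart at either later time. These 4 counts moved by over 1.5 times with the matching rule: they were 5400, 11258, 1962 and 10105 when identical bins were required, and 1344, 3106, 532 and 2709 with an FDR of at most 0.0001 on one side. With lists of equal length the last was 3019. The reference model without change of single contacts gave 1131, 2135, 543 and 2565 for the 4 counts as reported with list-wide factors. Without the factors, the form run first, it gave 2340, 4117, 1444 and 1167. Over the form with factors the 4 counts were 1.91, 2.59, 1.68 and 1.86 times as high, where lists simulated without change already gave 1.58, 1.52, 1.36 and 1.63. Over the form without they were 0.923, 1.34, 0.630 and 4.09 times as high, where lists without change gave 1.40, 1.52, 1.3 and 1.63. The uninjured-only count thus lay above the level without change in both forms, and the 3 counts of gained interactions, that at 4 dpa included, only in the form with factors. For the uninjured-only count, the form without factors is no separate support, because it gave 21059 interactions at 0 dpa against 28421 deposited. With factors, 1.86 stood against 1.63 from 3 refits, whose spread is not given. The form with factors in turn gave 22720 interactions at 4 dpa against 26988 deposited. The overlap of 909 was 42.1% of the 1 dpa set, against 48.0% in the model with factors and 61.7% in the form without. Lists simulated without change exceeded the model by less for the overlap than for the 1 dpa set, so both model shares are too high. The observed share was thus not set apart from the form with factors. It lay below the form without, by a smaller margin than these shares give. A level of 277 for independent lists was taken over all 43117 pairs. These include 0 dpa pairs, which neither set can hold, and matches within 1 bin were not allowed for, so it is no chance level for 909. Part of the overlap may come from the shared 0 dpa list.

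**Figure D1:**
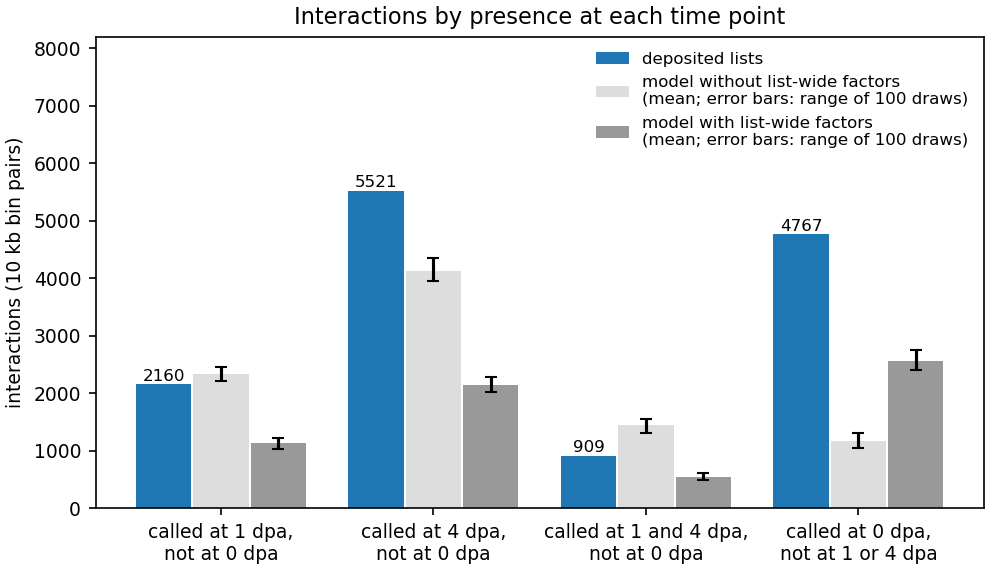
Number of interactions (10 kb bin pairs, vertical axis) in 4 presence sets, where "not at" means no called pair with both anchors within 1 bin. Blue bars are the deposited lists, and grey bars the mean of 100 draws of the reference model without and with list-wide factors, with error bars for the range of the draws; the deposited 1 dpa count of 2160 lies below the form without factors and above the form with them. Lists simulated without change also exceed the model, so the height of a blue bar over a grey one is no measure of change.

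The contacts called as gained by 4 dpa spanned longer distances than those called as lost. By the median, expected counts of shared 20 kb pairs were 1.28 times as high at 4 as at 0 dpa. Their observed counts were 1.12 times as high. Over 500 kb and up to 1 Mb these ratios were 1.05 and 1.07. Short pairs thus had a higher background to pass at 4 dpa, which is left undecided as a cause. The shortest span in each list was 20 kb, so the median of the lost set lay close to this floor. The 5521 gained interactions had a median span of 110 kb (110 to 120), against 30 kb (30 to 30) for the 6499 interactions of uninjured fins without a 4 dpa counterpart. The difference of 80 kb compared with 6.5 kb in the reference model with factors and -19.1 kb in the form without. Gained contacts were longer than lost ones on 25 of 25 chromosomes, by 40 to 110 kb. All chromosomes come from the same lists, so they are not replicates. Of the 0 dpa interactions of at most 50 kb, 34.8% had no 4 dpa counterpart, against 14.5% over 50 and up to 100 kb, 11.1% up to 200 kb, 11.7% up to 500 kb, 21.0% up to 1 Mb and 24.1% over 1 Mb. On the gained side the short class did not stand apart: 20% of the 4 dpa interactions of at most 50 kb had no 0 dpa counterpart, against 14.8%, 20.7%, 27.3%, 31.2% and 21.1% in the same longer classes. At 1 dpa, the gained interactions had a median span of 70 kb (60 to 70), within the draws of the form with factors (60 to 90) and without (50 to 70). The 8231 interactions of uninjured fins without a 1 dpa counterpart had a median span of 30 kb (30 to 40), below the draws of both (40 to 50 and 50 to 60). At least 1 anchor bin in the 0 dpa list was found for 59.2% of the contacts gained at 4 dpa and 60.5% of those gained at 1 dpa. Of the lost contacts, 55.6% had an anchor bin in the 4 dpa list and 49.8% of those without a 1 dpa counterpart had one in the 1 dpa list; no chance level was computed.

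**Figure D2:**
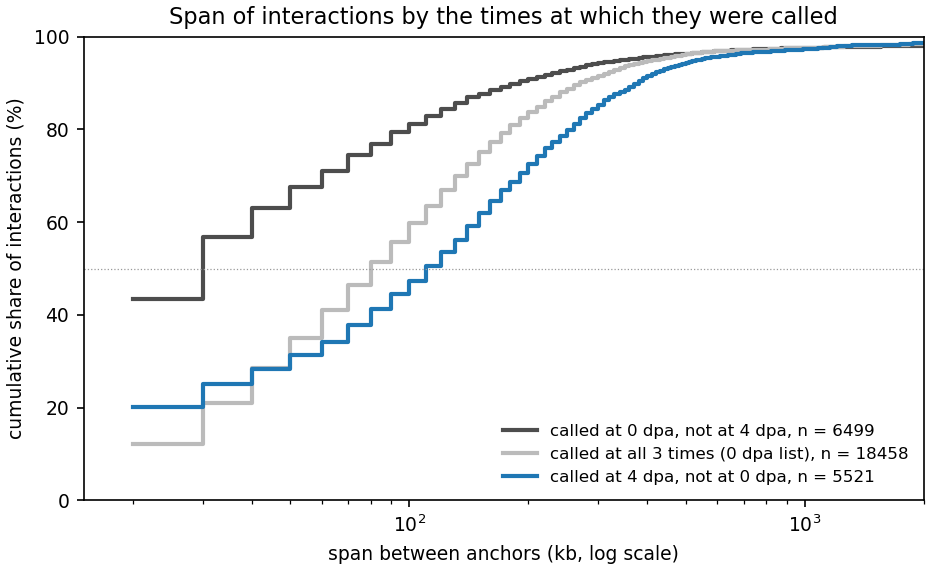
Cumulative share of interactions (%) by span between anchors (kb, log axis) for 0 dpa interactions without a 4 dpa counterpart (lost), 0 dpa interactions with counterparts at both 1 and 4 dpa, and 4 dpa interactions without a 0 dpa counterpart (gained). The lost set reaches its median at 30 kb and the gained set at 110 kb.

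At 4 dpa, the strongest gained contact lay on chromosome 21, between 42830001–42840000 and 44110001–44120000. It had 28 counts and was 23.5 times the expected count (95% interval 15.6 to 34). A contact on chromosome 23, between 19130001–19140000 and 19690001–19700000, was 18.5 times expected (11.6 to 28.0). A contact on chromosome 6, between 6250001–6260000 and 7820001–7830000, was 16.2 times expected (10.1 to 24.5). At 1 dpa, a contact on chromosome 9 between 18250001–18260000 and 18700001–18710000 was 14.0 times expected (8.95 to 20.8). One on chromosome 17, between 40950001–40960000 and 41320001–41330000, was 10.5 times expected (6.77 to 15.4) at 1 dpa, was also called at 4 dpa and belonged to a cluster of 4 called pairs. Its right anchor, 41320001–41330000, had 3 interactions at 0 dpa and 8 at both 1 and 4 dpa. Its rise to 1 dpa of 5 became 0 with summits alone, 1 at a count of at least 20 and 1 for spans up to 200 kb. Among contacts of uninjured fins without a later counterpart, a pair on chromosome 10 between 24780001–24790000 and 25110001–25120000 was 12.7 times expected (8.48 to 18.2). A pair on chromosome 25 between 3490001–3500000 and 3640001–3650000 was 12 times expected (7.93 to 17.5). Of the 8 pairs named by rule in each set, 5 at 1 dpa and 4 at 4 dpa had no 0 dpa counterpart when anchors within 2 bins counted, and 0, 3 and 0 of those of the 1 dpa, 4 dpa and uninjured sets were left without singletons. Up to 1 Mb, 4, 1 and 5 of them were left. The pairs described above are only part of those named. Of these, the 4 dpa pairs of chromosomes 21 and 6 spanned 1.28 and 1.57 Mb, at low expected counts of 1.19 and 1.36. Several other named pairs with high values also spanned over 1 Mb, where the expected count was low. The highest at 1 dpa spanned 44.6 Mb, at 21.9 times an expected count of 1.01. That of the uninjured set spanned 40.5 Mb, at 19.9 times an expected count of 1.01.

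Individual anchors had many more or many fewer called partners at later times. The bin at 8450001–8460000 of chromosome 9 had the most interactions in uninjured fins, 33, and had 20 at 1 dpa and 12 at 4 dpa. The bin at 46840001–46850000 of the same chromosome went from 15 at 0 dpa and 11 at 1 dpa to 28 at 4 dpa, the most in that list, over the same reach of 580 kb. On chromosome 20, the bin at 22470001–22480000 had 11, 15 and 21 interactions over a reach of 670 kb. On chromosome 23, the bin at 32940001–32950000 had 3, 6 and 13. On chromosome 10, the bin at 33150001–33160000 had 8, 4 and 19. Among anchors with fewer called partners later, the bin at 17460001–17470000 of chromosome 13 had 22, 9 and 10, and the bin at 32070001–32080000 of chromosome 2 had 12, 5 and 1. For pairs kept in the same bins, the 4 over 0 dpa ratio of observed over expected was 1.08 at the chromosome 9 bin at 46840001. It was 1.09, 1.12 and 0.866 at the bins of chromosomes 20, 23 and 10. At the chromosome 9 bin at 8450001 it was 0.751. At the bins of chromosomes 13 and 2 it was 0.984 and 0.807, the last from 1 pair. Kept pairs changed less than the number of called partners, and in the other direction at chromosome 10. They had to be called at both times, which limits the change they can show. At 1 dpa the largest rises were small, from 3 to 9 interactions at 34270001–34280000 of chromosome 12 and from 4 to 10 at 6210001–6220000 of chromosome 21. The largest rise to 4 dpa, 13, and the largest fall, 21, compared with at most 10 and 13 in 100 draws of the model with factors, and at most 13 and 9 in the form without. Lists without change gave on average 1.3 and 1.03 times the rise and fall of the refitted form with factors, and 1.14 and 1.08 times those of the form without. The rise of 13 is thus not set apart from the model, while the fall of 21 lay above the draws of both forms by more than this. The draws are independent from pair to pair, with no term shared by the pairs of an anchor. They therefore cannot say whether such a fall is unusual for an anchor. The largest rise to 1 dpa, 6, was within the draws of both forms, and the largest fall, 13, was within those of the form with factors (8 to 20) and above those of the form without (5 to 11). These differences depended on the calls counted. With cluster summits alone, since neighbouring pairs are not independent, the chromosome 9 bins at 8450001 and 46840001 differed between 4 and 0 dpa by -3 and 3, the chromosome 23 bin by 3, the bins of chromosomes 20 and 10 by 1, and those of chromosomes 13 and 2 by 0. At an FDR of at most 0.0001, the chromosome 9 bin at 8450001 differed by -13, the bins of chromosomes 13 and 2 by -5 and -6, and those of chromosomes 23 and 10 by 6 and 2. With lists of equal length, the bins of chromosomes 13 and 2 differed by -5 and -6 and the chromosome 10 bin by 5. The chromosome 9 bin at 46840001 differed by 7 at a count of at least 20 and by 5 up to 200 kb, where the bins of chromosomes 10, 20 and 13 differed by 7, 2 and -6. Between 1 and 0 dpa, the falls of 13 at the chromosome 9 bin at 8450001 and at the chromosome 13 bin became -4 and -5 with lists of equal length and -1 and -2 with summits alone. The chromosome 13 fall was -8 at an FDR of at most 0.0001 and -7 up to 200 kb. The rises to 1 dpa at the bins of chromosomes 12 and 21 became 1 and 0 with summits alone, and the chromosome 12 rise was 3 at an FDR of at most 0.0001.

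**Figure D3:**
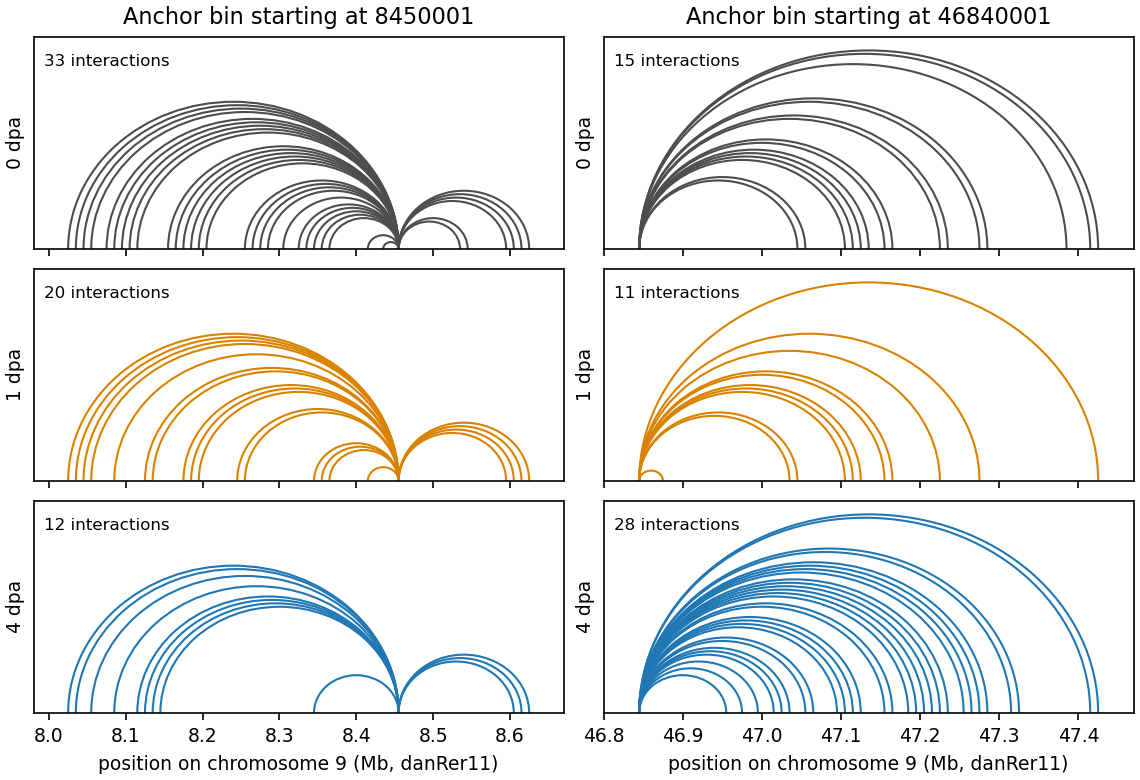
Interactions of a pair of anchor bins of chromosome 9 at 0, 1 and 4 dpa, drawn as arcs from the anchor to each partner bin (position in Mb, danRer11). The anchor at 8450001 has 33, 20 and 12 interactions and the anchor at 46840001 has 15, 11 and 28.

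Contacts called in the same bins at 0 dpa and later were mostly of similar strength. Only pairs that passed the calling limits at both times could be compared. Pairs that changed strongly may be missing, so the similarity is partly fixed by this selection. At 1 dpa, 13312 pairs were shared with 0 dpa, and their median ratio of observed over expected counts was 0.944; 231 were at least 1.5-fold higher and 914 at least 1.5-fold lower. At 4 dpa, 15730 pairs were shared, with a median ratio of 0.899, 303 higher and 1558 lower. The split into higher and lower pairs moved with the scaling. With raw counts scaled by their total, 558 pairs were higher and 515 lower at 1 dpa, and 774 were higher and 725 lower at 4 dpa. With ratios centred on their median, 425 were higher and 561 lower at 1 dpa, and 684 and 685 at 4 dpa. Centring shifts all ratios alike and largely fixes its own split, while raw counts leave out the expected count, whose ratio between times varied with span. The model with factors gave 218 higher and 944 lower at 1 dpa, and 170 and 1355 at 4 dpa; the form without gave 482 and 417, and 394 and 605. The expected count of shared pairs was 1.28 times as high at 4 as at 0 dpa for spans of 20 kb, and 1.05 times for spans over 500 kb and up to 1 Mb. Their observed count was 1.12 and 1.07 times as high in these classes, by the median, and 0.933 times over 1 Mb.

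**Figure D4:**
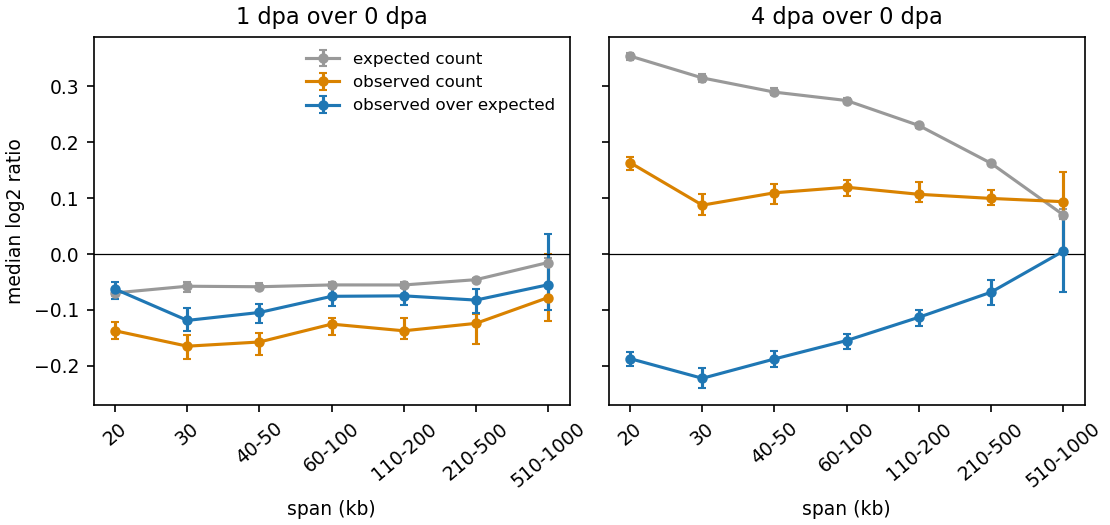
Median log2 ratio of expected counts, observed counts and observed over expected counts of shared pairs by span (kb), 1 over 0 dpa on the left and 4 over 0 dpa on the right, with 95% order-statistic intervals. At 4 dpa the expected counts rise most at 20 kb, by 0.35 on the log2 scale.

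Among pairs called at all times, the contact on chromosome 12 between 34270001–34280000 and 34370001–34380000 rose from 22 to 61 counts at 1 dpa, a ratio of 2.49 (1.51 to 4.26) in observed over expected. At 4 dpa it had 56 counts. On the same chromosome, the contact between 23420001–23430000 and 23640001–23650000 rose from 14 to 41 counts at 4 dpa, a ratio of 2.42 (1.29 to 4.80). The contact on chromosome 7 between 5960001–5970000 and 6430001–6440000 fell from 46 to 12 counts at 1 dpa, a ratio of 0.269 (0.130 to 0.516), and had 45 counts at 4 dpa. The contact on chromosome 11 between 44230001–44240000 and 44530001–44540000 had 43 counts at 0 dpa and 16 at both later times, with ratios of 0.355 (0.186 to 0.642) at 1 dpa and 0.333 (0.175 to 0.603) at 4 dpa. The contact on chromosome 5 between 28810001–28820000 and 28840001–28850000 went from 72 counts at 0 dpa to 63 at 1 dpa and 33 at 4 dpa, a ratio at 4 dpa of 0.335 (0.215 to 0.512). These pairs are the extremes of 10726, and their intervals are not adjusted for that choice. Of the 8 pairs selected in each comparison, 1 was left when a count of at least 20 was required at both times.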

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

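Among 18 anchors and 15 shared contacts, selected by their number of interactions or size of change, 3 anchors and 3 contacts lay on opposite sides of their 0 dpa value at 1 and 4 dpa. With 1 list per time point these differences were not tested, and for the contacts of chromosomes 13 and 23 the value at the other time hardly differed from that at 0 dpa. From 1 to 4 dpa, the bin at 46840001 of chromosome 9 gained 17 interactions, having had 4 fewer at 1 dpa than at 0 dpa and 13 more at 4 dpa. The bin at 33150001 of chromosome 10 gained 15 from 1 to 4 dpa. The bin at 32010001 of chromosome 2 had 16, 18 and 13 interactions at 0, 1 and 4 dpa, a difference of -5 from 1 to 4 dpa. The contact on chromosome 13 between 44190001–44200000 and 50760001–50770000 had an observed over expected count of 0.364 times its 0 dpa value at 1 dpa and 1.03 times at 4 dpa, with 33 counts at 0 dpa and 34 at 4 dpa. On chromosome 6, the contact between 12960001–12970000 and 30490001–30500000 had 0.30 times its 0 dpa value at 4 dpa and 1.18 times at 1 dpa, with 40 counts at 0 dpa and 47 at 1 dpa. On chromosome 23, the contact between 41980001–41990000 and 42240001–42250000 had 0.344 times its 0 dpa value at 4 dpa and 1.00 times at 1 dpa, with 37 counts at both 0 and 1 dpa.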

How the results depend on the processing

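The form of the reference model, the span limit of 1 Mb, the differences of gained and lost or of higher and lower counts, the spans of gained and lost sets and all named items were examined under alternatives added after seeing the data. Of 291 alternative values, 171 stayed within their limits (1.5 times for counts, the 95% interval for medians), 113 moved beyond them and 7 changed direction; the cause was not tested except where the setting itself fixes it, as with fewer pairs counted. Gained contacts at 4 dpa kept a longer median span (70 to 120 kb) than lost ones (20 to 50 kb) under each alternative run. At an FDR of at most 0.0001 the lists held 18475, 12077 and 17333 interactions at 0, 1 and 4 dpa, and as cluster summits 10526, 7665 and 9933. With identical bins required, 5400 interactions at 1 dpa, 11258 at 4 dpa and 1962 at both times had no 0 dpa counterpart, and 10105 of uninjured fins had no later one. With an FDR of at most 0.0001 on one side these were 1344, 3106, 532 and 2709, and with lists of equal length the last was 3019. Gained minus lost interactions at 4 dpa, -978 as reported, were -632 with the one-sided limit, -598 for summits, -1542 at a count of at least 20, -298 with lists of equal length, -1886 up to 200 kb and -481 without singletons. Shared pairs 1.5-fold higher and lower at 1 dpa were 425 and 561 when centred (difference -136), 558 and 515 by raw counts (43, against -683 as reported) and 82 and 517 at a count of at least 20 (-435). At 4 dpa they were 684 and 685 when centred (-1) and 774 and 725 by raw counts (49, against -1255 as reported), and 91 were higher at a count of at least 20. Without list-wide factors in the reference model, the form run first, the observed count over the simulated one turned from above to below 1 for 1 dpa interactions without a 0 dpa counterpart (1.91 to 0.923), for those at both times (1.68 to 0.630) and for shared pairs higher at 1 dpa (1.06 to 0.479) and at 4 dpa (1.78 to 0.770), and from below to above 1 for pairs lower at 1 dpa (0.969 to 2.19). It stayed above 1 for 4 dpa interactions without a 0 dpa counterpart (2.59 to 1.34, the latter below the 1.52 of lists without change) and for uninjured-only interactions (1.86 to 4.09). The 4.09 came from the form that fell short of the deposited 0 dpa list. No paired analysis was possible because the lists hold 1 value per time point and carry no replicate numbers, and no replicate could be left out for the same reason. Other settings intended for genes, gene lists and motifs were not run, since no annotation or sequence of the build was used here. Depth limits all absences: a contact that was not called may lie just under a count of 12 or under 2 times its expected count, and the one-sided limit, which asks for a clear call at the later time alone, left 1344 and 3106 interactions at 1 and 4 dpa.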

Other observations

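The tests of the shorter 1 dpa list and of the contacts over 5 Mb were settled after related results were seen, while those of the span difference were written before the values they measure.

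The longer span of contacts gained by 4 dpa was set against both counting noise near the calling limit and the authors' background. Among calls far from the limit, at an FDR of at most 1e-08, the difference of median span between gained and lost contacts was 125 kb (bootstrap 95% interval 90 to 155, 374 gained and 527 lost), which argues against noise near the limit as the whole cause. Each pair was also required to pass under the span profile of the other list's background, with the median change of background taken out. The difference was then 80 kb (70 to 80), as large as deposited. This step could only remove called pairs and left 5321 gained and 5782 lost. It could not restore short 4 dpa pairs that had failed under the higher background. The steeper background at 4 dpa is thus left undecided as a cause. Differences between pools, in the share of cell types in the fin and in ligation or cross-linking stay open and were not tested. A shift from short to longer called contacts during regeneration, relative to the authors' expected counts, may be a hypothesis for follow-up, found and tested on the same lists. The observed counts of shared pairs did not themselves fall at short span at 4 dpa. Their median ratio to 0 dpa was 1.12 at 20 kb and 1.07 over 200 and up to 500 kb.

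The shorter 1 dpa list was set against depth and counting noise, and the reading of both tests was revised after their values were seen. Thinning the 0 dpa list by the count ratio of strong 4 dpa pairs left 21827 calls, within 1.2 times the 18712 of the 1 dpa list, so the criterion written first was met; scaling by the expected counts of shared pairs, a measure added afterwards, left 25836 calls and did not meet it. The model with equal strength at all times and no list-wide factor gave 19562 calls at 1 dpa, which also met the criterion written first, but was then set aside because the same model gave 21059 calls at 0 dpa against 28421 deposited. That model's own ratio of 1 to 0 dpa calls was 0.929 (range of the draws 0.913 to 0.941) against 0.658 deposited. The ratio rests on a 0 dpa list that the model made too short, so it cannot decide on counting noise at equal strength. Depth and counting noise stay undecided, and a biological difference stays open as untested.

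Contacts over 5 Mb numbered 366 at 0 dpa, 343 at 1 dpa and 335 at 4 dpa, with a median of 18.5, 17.9 and 16.4 times the expected count. A candidate explanation is that the Ekkwill genome or the assembly places these sequences differently, so that the pairs lie close together in the fish. Such pairs would stay at all times: 60.4% (95% exact interval 55.2 to 65.4) of those at 0 dpa were the same pair in all lists, but shorter pairs matched on count and margin reached 63.0%, so the order of the sequence cannot be told apart from ordinary strong contacts. Repeats of chromosome 4 would put most such pairs there, and 13.7% (10.3 to 17.6) lay on it, which argues against them as the main source although 3.72% of all 0 dpa interactions do.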
